A study of Sorghum bicolor with 6 samples.

How the data were processed

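RNA-seq was carried out on leaf tissue of 4-week-old Sorghum bicolor in 6 libraries, 3 from empty vector plants and 3 from SbGhd7 overexpression plants. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I, and made into libraries with the NEBNext Ultra RNA kit. Per the submitters' processing notes, HISAT2 (version 2.2.1), StringTie (version 2.2.1) and DESeq2 (version 2.11.40.7) were used. The notes used here give these tools no roles, and the genome build, strand setting and filters are not given in the sources used here. The gene identifiers of the deposited files end in v3.2.

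The authors deposited 1 file per library, each holding 1 whole number per gene model for 34129 gene models, with no scaling between libraries. The deposited values were treated as estimated counts, made by the authors with the tools named above as far as the submitters' processing notes tell. They are whole numbers, so rounding changed none, but in every library between 2.91 and 3.57 times as many genes had the value 2 as the value 1, which single reads counted once would not give. How a value relates to 1 sequenced fragment is not known, so intervals and floors based on counts cover counting error only and are, if anything, too narrow. Library totals ranged from 27844391 to 35830080. Without knowledge of strand, overlapping and antisense genes could not be told apart, and related gene copies may share reads.

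Groups and replicate numbers were taken from the sample titles. All 6 were kept as separate libraries, as titled. The closest pair, empty vector replicates 1 and 2, had a median chi-square per gene of 1.98 (mean 7.12), against medians of 4.19 to 7.77 for the other pairs of one group. Because the sampling noise of the values is not known, whether these 2 are repeats of one sample could not be told, and a fit with both summed is given with the alternatives. The replicate numbers were not treated as pairs, and the check is given with the alternatives.

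Genes were filtered with filterByExpr (20820 of 26611 genes with a count were tested), normalised by TMM, and tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust, R 4.3.3) in a design with the group as the only term and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. CPM values are TMM-scaled and computed from the deposited counts of the tested genes. The common biological coefficient of variation was 0.221. On simulated data with the means, dispersions and library sizes of this comparison (20528 genes tested, 198 of them changed), the same procedure recovered 53.0% of the genes changed 2-fold and 78.6% of those changed 4-fold, with 11 false calls among 141. In the data 53.3% of the tested genes were called. The adjustment is stricter when few genes change, so these recovery rates do not describe the real comparison. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation of 0.01), and again with an estimated correlation and with fry, adjusted over the 4 lists tested. DESeq2 1.42.0 and limma-voom were used as alternatives.

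Before the data were examined, 31 gene lists were fixed, together with the rule for named genes. The reference table used here (32945 genes) matched none of the 34129 identifiers and holds no descriptions. The 22 lists defined only by protein description therefore could not be built, among them the marker lists for dividing tissue, senescence and epidermis. The other 9 lists rest on identifiers alone. All of these but flowering regulators and plant stature were also meant to take members by description. Any such members are missing, so these lists are small picks of known genes and may not represent their pathways. The names attached to the identifiers of the 9 lists were fixed before the data were examined from general knowledge of published sorghum gene names. No table used here pairs them with the identifiers, so the names could not be checked. Of these 9 lists, flowering regulators, circadian clock, C4 and Calvin cycle, and phenylpropanoid and lignin had enough members for a set test. The short lists were dhurrin, plant stature, the florigen family (CN8, CN12 and CN15), the phytochromes (PHYB and PHYC) and CONSTANS-like genes (CO), and their members are given singly. The rule named SbGhd7, every flowering regulator, the 10 genes with the largest rise and the 10 with the largest fall (adjusted p under 0.05, mean CPM of 1 or more, no overlap between groups), and the 3 members with the smallest p of each other list with 3 or more changes. Because the identifiers are not paired with names, only 2 of the 10 are named in each direction. One member of the phenylpropanoid list is counted in its set test but not reported here. Positions in the genome are not given, because no annotation matched the identifiers.

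The alternatives fixed in advance were DESeq2 size factors, library size alone and upper quartile scaling, no filter and a filter of CPM of 1 or more in 3 libraries, DESeq2's Wald test, limma-voom, the replicate number as a block, leaving out each library, a log2 fold change of at least 1, an adjusted p under 0.01, an estimated correlation, and fry. Settings for FPKM or TPM values did not apply. Halved values and empty vector replicates 1 and 2 summed into 1 library were added after seeing the data.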

Results

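Leaf RNA from 4-week-old sorghum (Sorghum bicolor) was sequenced from plants carrying an empty vector and from plants overexpressing SbGhd7 (SbGhd7 OE), with 3 libraries in each group. SbGhd7, also known as Ma6, encodes a CCT-domain protein of the photoperiodic flowering pathway. The comparison addresses which leaf transcripts differ when this flowering regulator is overexpressed. The deposited values summed to between 27844391 and 35830080 counts per library, and between 23178 and 23956 of the 34129 gene models had a value above 0. The labels do not say whether the 3 libraries of a group came from separate plants or transformation events, so the p-values measure the spread between these libraries, which may be partly technical. Fold changes are given for SbGhd7 OE over empty vector, with their standard error (SE) and 3 libraries per group, and adjusted p-values come from edgeR's quasi-likelihood test unless another test is named.

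The SbGhd7 transcript (Sobic.006G004400) was low in the control leaves and abundant in the overexpression leaves. Its values were 35, 60 and 35 counts in empty vector replicates 1, 2 and 3, and 17295, 10339 and 20367 counts in SbGhd7 OE replicates 1, 2 and 3. In normalised terms it stood at 1.34 ± 0.532 CPM (SD, n = 3) in the controls and at 571.1 ± 208.2 CPM (SD, n = 3) in SbGhd7 OE. The log2 fold change was 8.75 (SE 0.454, adjusted p = 1.0e-05), a 429.5-fold difference. An exact two-sided permutation test of the log2 CPM values gave p = 0.1, the smallest value that 3 against 3 libraries allow. All 6 libraries therefore matched their labels for the overexpressed gene.

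The leaf transcriptomes of the 2 groups were widely different. Of 20820 genes tested, 11087 (53.3%) changed at an adjusted p under 0.05 in edgeR, of which 5829 were higher and 5258 lower in SbGhd7 OE. A change of at least 2-fold was fitted for 3379 of the higher genes and 2419 of the lower ones, and a change of at least 8-fold for 824 and 281. The 3 values of one group lay entirely above or below those of the other for 13320 genes (64.0%), against the 10% expected by chance. Spearman correlations across the tested genes were 0.976 to 0.994 between libraries of one group and 0.872 to 0.897 between libraries of different groups, a description over genes that are not independent replicates. The first principal component held 78.3% of the variance and separated the groups. Empty vector replicate 3 and SbGhd7 OE replicate 2 stood apart from the others of their group on the second component, which held 7.71%.

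**Figure D1:**
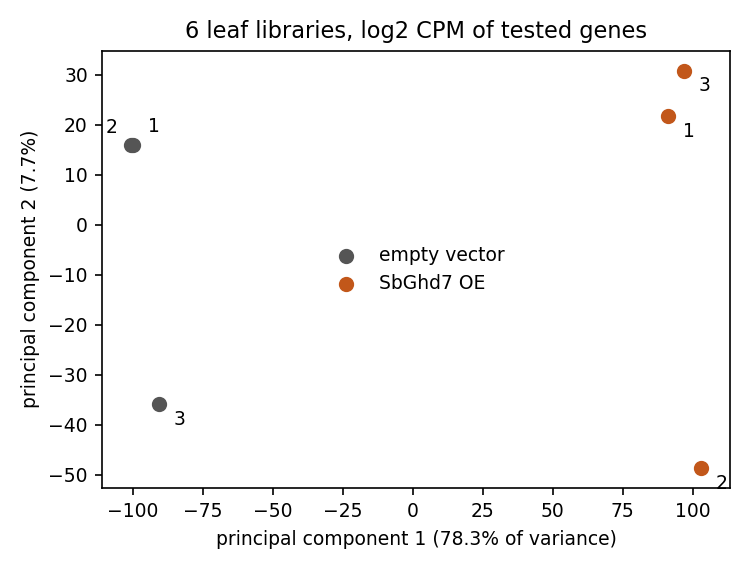
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library, numbered by replicate and coloured by group. The groups lie on opposite sides of component 1 (78.3% of the variance), and empty vector replicate 3 and SbGhd7 OE replicate 2 have the lowest values on component 2 (7.71%).

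The genes with the largest fitted changes were nearly absent from one of the groups. Of the 10 genes with the largest rise, 8 had no count in any control library, and of the 10 with the largest fall, 6 had no count in any SbGhd7 OE library. Their identifiers are not paired with names in the sources used here. Sobic.005G175900 had 0 counts in all 3 controls and 59, 607 and 145 counts in SbGhd7 OE (adjusted p = 0.0089). Against a floor of 3 counts over the control group it was at least 298.8-fold higher. Without SbGhd7 OE replicate 2, which held most of its counts, it was at least 116.1-fold higher. These bounds, and those below, hold only if each count stands for a separate fragment, which is not known. With values halved, the fitted log2 fold changes of Sobic.005G175900, Sobic.006G127900 and Sobic.003G026600 were 10.14, -10.61 and -9.97, against 11.13, -11.61 and -10.97. Sobic.003G237600 rose from 0.0632 ± 0.109 CPM to 109.1 ± 24.5 CPM (SD, n = 3 each), with all 7 of its control counts in replicate 3 (log2 fold change 10.5, adjusted p = 1.2e-05; without that library 14.6, adjusted p = 2.4e-05). Sobic.006G127900 had 446, 557 and 215 counts in the controls and none in SbGhd7 OE, at least 367.3-fold lower (adjusted p = 4.3e-04). Sobic.003G026600 had 285, 308 and 198 counts in the controls and none in SbGhd7 OE, at least 238.5-fold lower (adjusted p = 5.8e-05). Across all gene models, 84 had no control count and at least 10 counts in every SbGhd7 OE library, and 32 showed the opposite pattern.

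Among 14 flowering-time regulators, the florigen-family gene CN8 fell to 1 count in the whole SbGhd7 OE group, the phytochrome genes PHYB and PHYC and the clock-associated genes GI and ELF3 fell between 1.76-fold and 3.76-fold, and the morning clock gene LHY rose 30.8-fold. A second ELF3 copy rose 1.41-fold. Of the 10 members with enough counts to test, 2 rose, 5 fell and 3 did not pass the test. Adjusted over the list alone, 8 passed. Because 53.3% of all tested genes were called, such a count alone does not set the list apart. As a set, the list had a median log2 fold change of -0.61 and did not pass the camera test (adjusted p = 0.080 with the preset correlation, adjusted p = 0.16 with an estimated correlation). That call rested on empty vector replicate 3, without which the list passed (camera adjusted p = 0.035). The self-contained fry test, which does not compare the list with other genes, gave adjusted p = 7.4e-04 towards lower values.

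CN8 (Sobic.009G199900), a relative of the florigen gene FT, had 42, 44 and 31 counts in the controls and 0, 1 and 0 counts in SbGhd7 OE. The ratio of summed counts, corrected for library totals, was 105.8 in favour of the controls (95% exact interval 18.6 to 4216, counting error only), and edgeR gave a log2 fold change of -6.26 (SE 0.814, adjusted p = 3.8e-04). The only SbGhd7 OE count was in replicate 2. Without that library the fitted log2 fold change was -8.21 and the gene had no count in the group. With values halved the log2 fold change was -5.27 (edgeR adjusted p = 5.2e-04). CN8 missed the alternative filter of CPM of 1 or more in 3 libraries, so it was not tested under that setting. EHD1 (Sobic.001G227900), an activator of florigen genes in rice and sorghum, had 0, 7 and 2 counts in the controls and none in SbGhd7 OE. CO (Sobic.010G115800), the CONSTANS orthologue, had 24, 20 and 5 counts against 0, 6 and 2. The FT relatives CN12 (Sobic.003G295300) and CN15 (Sobic.010G045100) had 0, 0 and 33 counts against none, and 3, 3 and 0 counts against 0, 4 and 3. These 4 genes fell below the count filter. In the fit without a filter their adjusted p-values were 0.16 for EHD1, 0.098 for CO, 0.13 for CN12 and 0.88 for CN15, so none of them passed. All 33 counts of CN12 were in empty vector replicate 3, and the summed counts of CN15 were 6 in the controls and 7 in SbGhd7 OE.

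The clock genes moved in both directions, in leaves whose time of harvest the labels do not give. LHY (Sobic.007G047400), a morning-phased MYB-type component of the circadian clock, rose from 24.6 ± 5.60 to 758.9 ± 220.03 CPM (SD, n = 3 each; log2 fold change 4.95, SE 0.285, adjusted p = 1.1e-05). ELF3 (Sobic.009G257300), part of the evening complex, fell from 122.7 ± 17.2 to 32.6 ± 4.29 CPM (log2 fold change -1.91, SE 0.150, adjusted p = 3.4e-05). GI (Sobic.003G040900), GIGANTEA, fell from 1430.1 ± 161.5 to 812.5 ± 76.4 CPM (log2 fold change -0.82, SE 0.155, adjusted p = 0.0026). A second ELF3 copy (Sobic.003G191700) rose by a log2 fold change of 0.50 (SE 0.136, adjusted p = 0.015), a call lost without empty vector replicate 1 or 2 or SbGhd7 OE replicate 1 (adjusted p = 0.063, 0.077 and 0.055). TOC1 (Sobic.004G216700), a dusk component, had a log2 fold change of 1.43 (SE 0.541) and missed the threshold (adjusted p = 0.056), with 56, 323 and 114 counts in SbGhd7 OE. Its value depended on single SbGhd7 OE libraries: without replicate 2 the log2 fold change was 0.58 (adjusted p = 0.22), and without replicate 1 it was 1.82 and passed (adjusted p = 0.0096). PRR37 (Sobic.006G057866), the floral repressor at Ma1, did not pass (log2 fold change -0.40, SE 0.376, adjusted p = 0.40). Of the 6 clock members 2 rose, 2 fell and 2 did not pass. All 6 are also among the flowering regulators, so these calls are counted there too and the 2 set tests are not independent. The clock set did not pass camera (adjusted p = 0.84 with the preset correlation, adjusted p = 0.84 with an estimated correlation). Over all tested genes 53.3% were called, so the number of clock genes called does not set them apart.

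Both red-light photoreceptor genes in the list fell. PHYC (Sobic.001G087100) fell from 202.8 ± 13.7 to 58.5 ± 3.79 CPM (SD, n = 3 each; log2 fold change -1.79, SE 0.115, adjusted p = 1.5e-05). PHYB (Sobic.001G394400) fell from 198.2 ± 13.8 to 83.8 ± 12.2 CPM (log2 fold change -1.24, SE 0.138, adjusted p = 1.8e-04). Ma2 (Sobic.002G302700), a maturity gene encoding a SET- and MYND-type lysine methyltransferase, did not pass (log2 fold change -0.34, SE 0.164, adjusted p = 0.11), but did without empty vector replicate 1 (log2 fold change -0.49, adjusted p = 0.038).

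**Figure D2:**
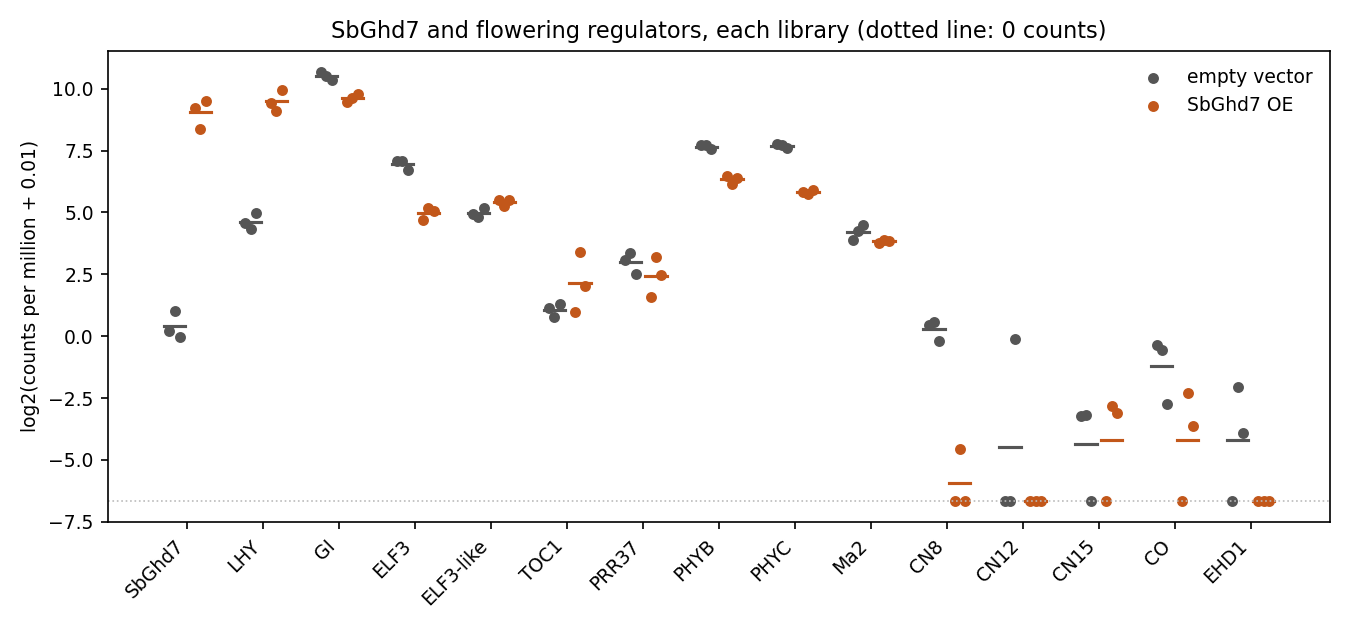
Expression of SbGhd7 and the 14 flowering regulators in each library, as log2 of CPM (over the deposited total) plus 0.01, with 1 point per library, a bar at the mean of the 3 log2 values and a dotted line at 0 counts. SbGhd7, LHY and the second ELF3 copy (ELF3-like) are higher in all 3 SbGhd7 OE libraries. CN8, PHYB, PHYC, ELF3, GI and, by a narrow margin, Ma2 are lower in all 3. CN12, CN15, CO and EHD1 have a library at 0 counts in at least 1 group.

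Genes of C4 photosynthesis changed in both directions. Genes for 4 enzymes that act in the mesophyll, where carbon dioxide is first fixed, rose between 2.25-fold and 20.6-fold, and the gene for a decarboxylase of the bundle sheath fell 1.99-fold. Of 9 C4 and Rubisco genes, 5 rose, 1 fell and 3 did not pass, and the same number, 6, passed when adjusted over the list alone. Of all tested genes 53.3% were called, and 65.0% of the 2082 with the highest mean expression. The number of list members called therefore does not by itself set the list apart. The list passed camera upwards (median log2 fold change 1.17, adjusted p = 4.0e-04 with the preset correlation, adjusted p = 0.036 with an estimated correlation). The 3 members with the smallest p-values were the carbonic anhydrase gene CA2 (Sobic.003G234400; log2 fold change 4.37, SE 0.221, adjusted p = 6.3e-06), its neighbour CA1 (Sobic.003G234200; 4.36, SE 0.266, adjusted p = 1.2e-05) and NADP-dependent malate dehydrogenase (Sobic.007G166300; 2.30, SE 0.191, adjusted p = 4.4e-05). CA1 went from 255.4 ± 77.6 to 5245.4 ± 679.3 CPM (SD, n = 3 each). CA1 and CA2 are related copies with nearby gene numbers, and CA2 held between 8.81% and 13.4% of the CA1 count in the 6 libraries. Whether reads were shared between them was not tested, so the value of CA2 is uncertain. The camera test of the list counted CA1 and CA2 as separate members. The other members are named after their values were seen. Phosphoenolpyruvate carboxylase (PEPC, Sobic.010G160700), the first carboxylating enzyme of the C4 cycle, rose from 3717.3 ± 322.2 to 16322.3 ± 2396.4 CPM (log2 fold change 2.13, adjusted p = 6.6e-05). Pyruvate, phosphate dikinase (PPDK, Sobic.009G132900), which regenerates its substrate, rose from 6666.8 ± 571.6 to 15029.2 ± 3674.3 CPM (log2 fold change 1.17, adjusted p = 0.0026). The bundle sheath decarboxylase NADP-ME (Sobic.003G036200) fell from 4211.0 ± 236.1 to 2113.0 ± 261.3 CPM (log2 fold change -0.99, adjusted p = 0.0012). Another carbonic anhydrase gene, CA3 (Sobic.003G234500), a second NADP-ME gene (Sobic.003G036000) and the small subunit gene of Rubisco, RBCS (Sobic.005G042000), did not pass (adjusted p = 0.42, 0.84 and 0.15). RBCS had a log2 fold change of -0.39, and it passed without empty vector replicate 3 (-0.61, adjusted p = 0.015). CA3 passed without SbGhd7 OE replicate 1 (log2 fold change 0.33, adjusted p = 0.043).

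Most of the listed genes of the phenylpropanoid pathway, which makes lignin precursors, rose. Of 9 members 8 rose, none fell and 1 did not pass, and 8 passed when adjusted over the list alone. Of all tested genes, 53.3% were called, 5829 upwards and 5258 downwards. The list passed camera upwards (median log2 fold change 2.73, adjusted p = 2.9e-11 with the preset correlation, adjusted p = 0.036 with an estimated correlation). C4H (Sobic.002G126600), cinnamate 4-hydroxylase, rose from 9.44 ± 0.636 to 142.5 ± 4.38 CPM (SD, n = 3 each; log2 fold change 3.92, SE 0.114, adjusted p = 2.0e-06). HCT (Sobic.004G212300), a hydroxycinnamoyl transferase, had a log2 fold change of 2.84 (SE 0.158, adjusted p = 8.8e-06). Another 5 members that rose, CAD, CCR, C3H, CCoAOMT and 4CL, had log2 fold changes of 2.91, 2.73, 2.45, 1.17 and 1.02. One gene for PAL (Sobic.004G220300), phenylalanine ammonia-lyase, did not pass (log2 fold change -0.31, adjusted p = 0.61). Its control counts were 1502, 1433 and 5658, and without replicate 3 of the controls its direction turned and it passed (log2 fold change 0.49, adjusted p = 0.024).

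The 3 biosynthetic genes of dhurrin, the cyanogenic glucoside of sorghum, rose more than 10.6-fold. CYP79A1 (Sobic.001G012300), the cytochrome P450 of the first step, rose from 29.7 ± 10.6 to 438.4 ± 175.03 CPM (SD, n = 3 each; log2 fold change 3.89, SE 0.412, adjusted p = 2.6e-04). CYP71E1 (Sobic.001G012200), the second P450, had a log2 fold change of 3.41 (SE 0.335, adjusted p = 1.7e-04), and UGT85B1 (Sobic.001G012400), the glucosyltransferase, of 4.35 (SE 0.252, adjusted p = 1.2e-05). DHR1 (Sobic.008G080400), a dhurrin-hydrolysing beta-glucosidase, fell slightly (log2 fold change -0.41, SE 0.138, adjusted p = 0.033), and this call was lost with the replicate number as a block (adjusted p = 0.074) and without empty vector replicate 1 or 2 or SbGhd7 OE replicate 1 or 3 (adjusted p = 0.085, 0.12, 0.079 and 0.053). All 4 members passed when adjusted over the list alone, in data where 53.3% of all tested genes were called. The list was too short for a set test.

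**Figure D3:**
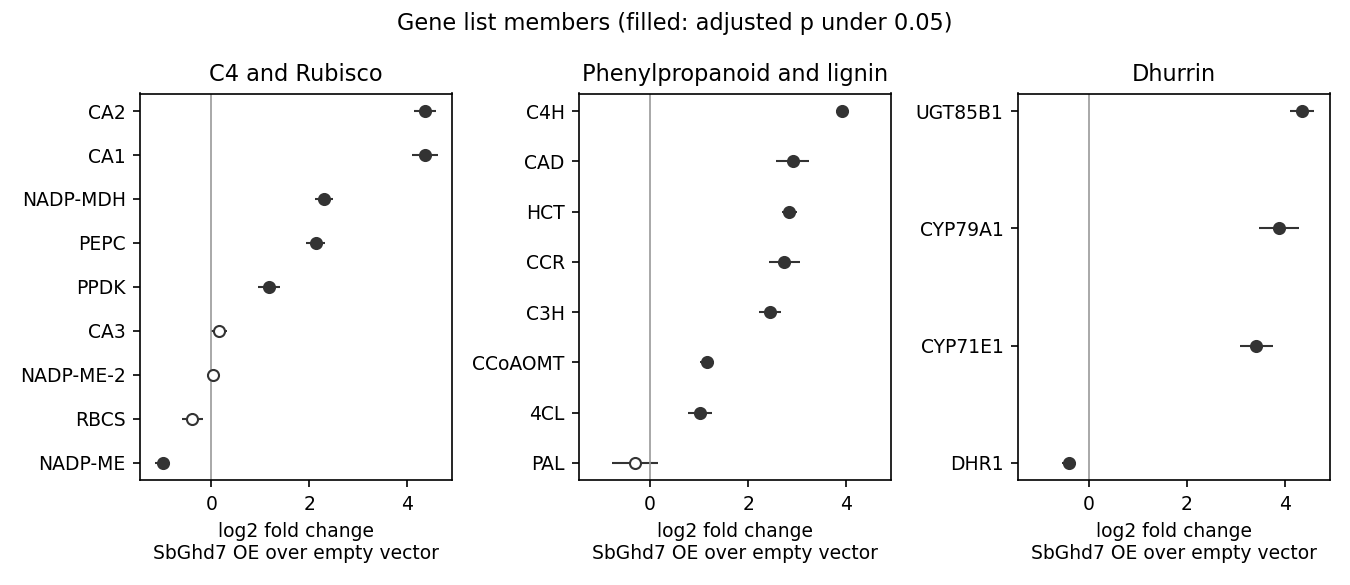
Log2 fold change of SbGhd7 OE over empty vector for members of the C4, phenylpropanoid and dhurrin lists, with bars of 1 SE from edgeR (3 libraries per group) and filled points for an adjusted p under 0.05. Of the 8 phenylpropanoid members plotted, 7 lie above 0, the 3 dhurrin biosynthetic genes lie between 3.41 and 4.35, and the C4 list spans -0.99 to 4.37.

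Plant stature genes did not pass the test. The dwarfing genes Dw3 (Sobic.007G163800), Dw1 (Sobic.009G229800) and Dw2 (Sobic.006G067700) had adjusted p-values of 0.62, 0.091 and 0.81, and at an unadjusted p under 0.05 none of the 3 passed in edgeR. Dw1 had a log2 fold change of -0.35 (SE 0.157) and passed with scaling by library size alone (-0.42, adjusted p = 0.047). The branching regulator Tb1 (Sobic.001G121600) had 0 counts in all 6 libraries.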

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

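The settings with halved values and with empty vector replicates 1 and 2 summed were chosen after seeing the data, and all others before. The rise of SbGhd7 and the 2 gene lists called by camera kept their side of the threshold under every alternative run. The count of 11087 changed genes varied with the setting, and asking also for a log2 fold change of at least 1 left 5798 genes. Under the other settings the count was between 7668 (adjusted p under 0.01) and 11396 (DESeq2's Wald test), and leaving out 1 library gave between 8850 and 10722. Of the genes called by DESeq2, 11005 were also called by edgeR. The share of higher genes among those called was 52.6%, and between 47.6% (library size alone) and 58.3% (log2 fold change of at least 1) otherwise. The log2 fold change of SbGhd7 lay between 8.52 and 9.09 when 1 library was left out. Camera was not run with DESeq2, and it called 2 lists in every other fit but the one without empty vector replicate 3, which called 3, as did fry, the third being the flowering regulators. Halved values gave 10929 genes, and summing empty vector replicates 1 and 2 gave 9066. With the replicate block 9848 genes were called, 9720 of them in common with the fit without it, and of the named genes called without the block only DHR1 was lost. The design without pairs was fixed in advance, with the replicate block as an alternative. Same-numbered libraries did not deviate together (correlations of 0.0055, -0.055 and -0.11), which is a weak check with 3 libraries per group. The labels name no batch, and 3 libraries per group are too few to rule out a shared one. Among single named genes, 598 of the repeated values kept direction and call, 6 kept direction and gained the call, 10 kept direction and lost it (each of the 10 for DHR1 or the second ELF3 copy), and 9 turned direction. All of the 9 had missed the threshold: the second NADP-ME gene (log2 fold change -0.038 with library size alone, -0.026 with upper quartile scaling, -0.073 to 0.085 when 1 library was left out), Dw2 (-0.037, -0.024, and -0.0062 to 0.11), Dw3 (-0.38 to 0.028 when 1 library was left out) and PAL (-0.61 to 0.49, the highest without empty vector replicate 3, where it also gained the call, adjusted p = 0.024). Of the 6 gains without a turn, TOC1 passed with DESeq2 (log2 fold change 1.44, adjusted p = 0.013) and without SbGhd7 OE replicate 1 (1.82, adjusted p = 0.0096), whereas without SbGhd7 OE replicate 2 its log2 fold change was 0.58 (adjusted p = 0.22). The cause was not tested. EHD1, CO, CN12 and CN15 had few counts to compare: their summed counts were 9, 49, 33 and 6 in the controls and 0, 8, 0 and 7 in SbGhd7 OE.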

Other observations

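The tests of harvest time and cell share were chosen after the results were seen, and those of library size, abundant genes and other splits before. With the tested genes ordered by mean expression and cut into 10 bins of 2082, 37.6% of the lowest bin and 65.0% of the highest were called in edgeR. A call is easier to reach at higher counts, so these shares do not show that highly expressed genes changed more often. The median log2 fold changes of the bins ran from -0.094 to 0.27, the highest in the lowest bin. Tested genes that followed each other in number on a chromosome, whatever untested gene models lay between, had weakly correlated changes. The Spearman correlation of log2 fold changes was 0.135 over 20770 such pairs, against -0.022 to 0.023 in 1000 shuffles within chromosomes. The permutation p over genes, not libraries, was 0.001, the smallest the shuffles can give. Whether related copies that share reads add to this correlation was not tested. For the 40 tested genes outside the 10 numbered chromosomes, 7 rose, 10 fell and 23 did not pass, and their median log2 fold change of -0.22 lay at percentile 11.5 of 10000 random lists matched on mean expression.

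Within groups, single libraries also differed. In empty vector replicate 3, 468 genes stood over 2-fold from both other controls while those lay within 1.2-fold of each other, against 108 and 129 genes for replicates 1 and 2. In SbGhd7 OE the numbers were 226, 385 and 203 for replicates 1, 2 and 3. PAL, at 5658 counts in empty vector replicate 3, is one of these genes, and CN12, too low to be tested, had all of its 33 counts in that library.

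The expression of 53.3% of the tested genes differed between 2 groups of leaves of one stated age. Thinning every library to 27844391 counts left 11032 changed genes, and removing the 100 most abundant genes left 11037, against 11087, so the count hardly depended on either. Little change was possible, because the fit already scaled by library size and the largest total was 35830080. The removed genes held 24.0% to 24.7% of the counts in the controls and 22.1% to 25.2% in SbGhd7 OE. Of the 10 splits of the 6 libraries into 3 and 3, only the real split (1 of 10) gave as many genes, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. The labels give no harvest day, leaf position or transformation event, so a difference in handling or line that follows the groups and an effect of SbGhd7 on the whole leaf both stay open.

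LHY rose while GI and ELF3 fell. A difference in harvest time between the groups is a candidate explanation, because these genes cycle through the day, and an altered clock in the overexpression plants is another that was not tested. The dusk gene TOC1 should move against LHY if the control leaves were taken near dusk and the SbGhd7 OE leaves near dawn. Other pairs of harvest times need not give this, and TOC1 was already low in the controls (2.07 CPM). Its log2 fold change of 1.43 missed the threshold in edgeR (adjusted p = 0.056). TOC1 passed, upwards with LHY, in DESeq2 (1.44, adjusted p = 0.013) and when adjusted over the list alone (adjusted p = 0.038). It also depended on single libraries (0.58, adjusted p = 0.22, without SbGhd7 OE replicate 2, and 1.82, adjusted p = 0.0096, without replicate 1). The direction of TOC1 therefore cannot decide the question. The explanations cannot be told apart, because no harvest time is given and no time course is at hand.

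Mesophyll enzymes of the C4 cycle rose while the bundle sheath enzyme NADP-ME fell. A larger share of mesophyll cells would raise transcripts confined to them by 1 factor. The log2 fold changes were 4.36 for CA1, 2.30 for NADP-MDH, 2.13 for PEPC and 1.17 for PPDK. CA1 exceeded PPDK by 3.19 (SE 0.346, taking the 2 genes as independent), a pair chosen after these values were seen. A shift in cell share alone is not enough if these transcripts are confined to the mesophyll, which was not checked. For the rise of CA1, PEPC and NADP-MDH, an effect of SbGhd7, of light or of harvest time on these genes was not tested.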
